A study of Pyrus pyrifolia with 66 samples.

How the data were processed

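Messenger RNA levels were measured in Japanese pear fruit with 66 one-colour (Cy3) Agilent microarrays, each on total RNA of 1 sample. The samples formed 22 groups of 3 arrays. Of these, 18 groups came from lines 1726 and 1703 of a Hosui by Hogetsu cross and 4 from lines 47341 and 47377 of a Taihaku by Akiakari cross. The array files named 17 slides, 14 for the first cross and 3 for the second, with up to 4 arrays on a slide. Per the labels, harvest dates are codes of 6 digits, read here as year, month and day, so that the first year of the Hosui by Hogetsu cross is 2012 and its second year 2013, and the other cross was sampled in 2014. Arrays of the 2 crosses were scanned on different days and read with different versions of the extraction protocol, so no level was compared directly between crosses.

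Per the file headers, Agilent Feature Extraction produced the scanner files, and their processed signal is a fluorescence intensity that was background-subtracted and detrended within each array, with low values replaced by a surrogate and no scaling between arrays. The same deposited files hold the mean spot intensity and the local background intensity, which served 1 alternative. Per the file headers, other columns hold marks of 0 or 1 for spots well above background, saturated spots and outlier spots. The authors also deposited a processed table of log2 values for 28101 probe names, relative to a value per probe that the table does not state. After centring per probe, each of its arrays correlated across probes with the scaled scanner signal at r of 0.976 or higher, with slopes of 0.996 to 1.02. How the authors chose those probes is not stated, so the scanner files were used for the values reported and the table for an alternative.

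Each array held 180880 spots, of which 176026 were not controls. These carried 113219 probe names and 99059 distinct 60-base sequences, and 11573 sequences went by several names. Control spots and outlier-marked spots (2 to 104 per array) were left out, and 1 saturated spot was found over all arrays. Processed signals were put on the log2 scale, each array's 75th percentile was subtracted, and spots of one sequence were averaged. A sequence is called a probe here and carries 1 of its names, and 38447 probes had 1 spot. A probe was kept when it was well above background on all arrays of at least 1 group of the fit, on at least 0.5 of its spots. This left 76346 probes for lines 1726 and 1703 and 72375 for lines 47341 and 47377, with 71030 in both.

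Well above background were 67.3% to 76.5% of spots per array, and the 75th percentile of the signal ranged from 980 to 3600. Precision is limited by the number of arrays, 3 per group.

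Differences were tested with limma (version 3.58.1, lmFit and eBayes) in R 4.3.3, with one mean per group and one spread per probe shared by the groups of a cross. That spread had 36 residual degrees of freedom in the first cross and 8 in the second. Benjamini-Hochberg adjustment ran over all probes kept, a probe was called at an adjusted p below 0.05, and calls of at least 2-fold were counted beside. Contrasts averaged years or harvests with equal weight. Other versions were statmod 1.5.0, arrow 21.0.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

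The comparisons, their tests, the alternatives and the rule for naming probes were fixed before the data were examined. The files give every probe the description Unknown and repeat the probe ID as its name, and no annotation was supplied. The 29 gene lists prepared for pear fruit therefore matched nothing and were not tested, and no function is given for any probe. Under the rule, probes without a name are printed by ID, at most 2 higher and 2 lower per comparison, with the largest log2 change among calls of the same sign in every harvest or year. A condition was added once the files had been seen, namely that the probe be well above background on all arrays of the comparison, because values at the background have no order. Probes shared by both crosses were ranked on the smaller of their 2 changes. A probe well above background on all arrays of one side and on none of the other was counted separately, with a lower bound for its fold change in which dim values were raised to the lowest value well above background on their array. Errors beside means are standard deviations (SD), and those beside changes are standard errors (SE) from limma.

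Scores for a set of probes are the mean of its higher members minus the mean of its lower members on each array. They were compared by two-sided permutation of labels within harvest, except that the test of the normal part exchanged years within each line. Enumeration was exact where the arrays allowed it and otherwise used 100000 draws, and 9 such tests were adjusted together. Set medians were compared with 10000 random sets drawn within 20 bins of mean signal, in 92 set tests. Splits of the samples exchanged labels within harvest (between years within part for the difference between years, between harvests within line and year for the July to August change), with 100 splits per comparison.

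Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, the authors' processed table, a block for the replicate number, a block for the slide, only the groups compared, all 66 arrays in one fit for the second cross, each year alone, the watercored part in place of the normal part, and leaving out each array in turn. Slide entered as a fixed block where a comparison could be estimated within slides. Otherwise it entered as a random block with a correlation of -0.0784 estimated from 5000 probes.

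The same steps were tested on simulated data with the layout of these arrays, with 50 changed probes for each fold. At a simulated 2-fold change the fit recovered 88% for watercored against normal flesh, 88% for normal flesh of line 1726 against line 1703, 100% for the lines in July and August, 96% for July to late August, and 62% for the second cross. For the difference between lines in the July to August change it recovered 68%, and for the difference between years in the watercored comparison 58%. At a 1.25-fold change recovery ran from 2% to 64% over the 7 comparisons. Each simulation changed 200 probes in all, far fewer than were called in the real data, so its adjusted threshold was stricter. The recovered shares thus do not measure how many real changes of these sizes were called.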

Results

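Watercore is a disorder in which pear flesh turns translucent as fluid fills the spaces between its cells. The series set seedling lines prone to watercore beside sib lines that were not, with messenger RNA profiles from 66 one-colour arrays. In a Hosui by Hogetsu cross, the susceptible line 1726 and the non-susceptible line 1703 were sampled at 4 harvests in each of 2 years. In the first year these fell on 13 July, 2 August, 23 August and 13 September, and in the second year on 11 July, 30 July, 20 August and 11 September. A change from July to late August, as given below, runs from the first to the third of these harvests in each year. In September the fruit of line 1726 were divided into a watercored part and a normal part. In a Taihaku by Akiakari cross, the susceptible line 47341 and the non-susceptible line 47377 were sampled on 5 and 20 August of a later year. Every group held 3 arrays, and this number limits the precision of each value. Well above background were 67.3% to 76.5% of spots per array. Each cross had 1 line of either kind, so a difference between lines belongs to those genotypes. The files give no gene name or description beyond the probe ID, so probes are given by ID and sequence.

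Within groups, arrays correlated with each other across probes at r of 0.957 to 0.996, and the median SD per probe was 0.10 to 0.30 on the log2 scale. In the arrays of lines 1726 and 1703, the component with the largest share of variance carried 48.5% and ordered the harvests from July to September. The next component carried 14.1% and set line 1703 above line 1726 at each harvest. All p-values below measure only the spread between these samples.

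**Figure D1:**
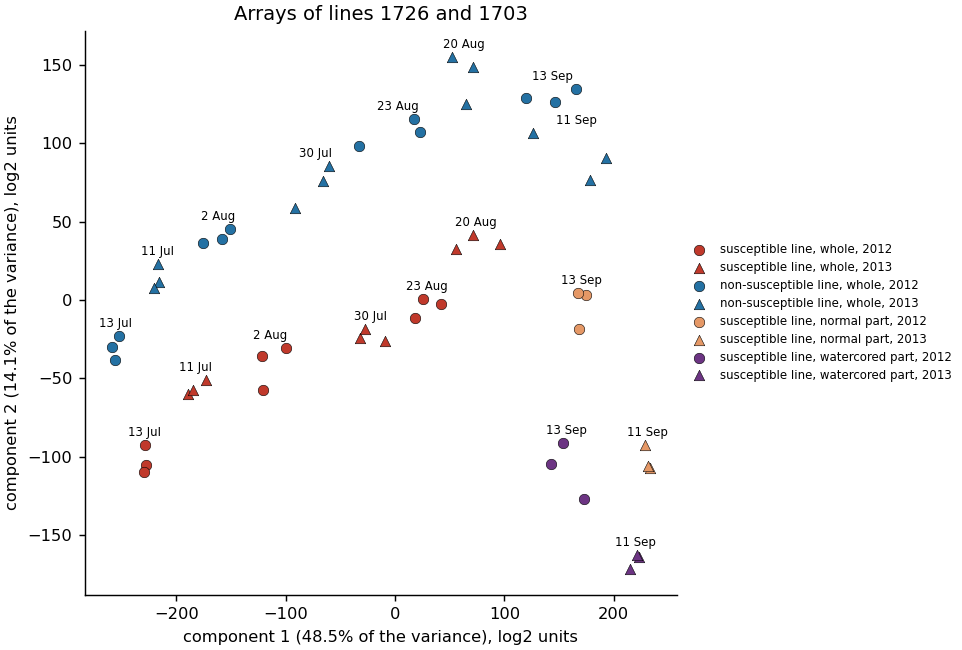
Each point is 1 of the 54 arrays of lines 1726 and 1703, placed on the 2 components with the most variance (48.5% and 14.1%, both axes in log2 units), with colour for line and part and shape for year. Harvests run from left to right, and in September the watercored arrays lie lowest within each year. Fruit whose labels name no part is marked whole in the figures.

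What set watercored flesh apart from normal flesh of the same line was asked in September of both years. Large differences were mostly increases in the watercored part, where 3941 probes were at least 2-fold higher and 807 at least 2-fold lower. Among differences of at least 4-fold, 1135 probes were higher and 27 lower. Probe NFW1_05_28tcv2 (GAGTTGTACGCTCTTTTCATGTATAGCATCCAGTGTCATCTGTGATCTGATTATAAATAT) was higher by 5.96 ± 0.44 on the log2 scale (SE), in 36 of 36 pairs of a watercored and a normal array taken across years. Its level relative to the 75th percentile was 1.98 ± 0.99 (SD, n = 3) in the watercored part of the first year against -4.71 ± 0.49 in the normal part. In the second year it was 2.42 ± 0.85 against -2.82 ± 0.66. NLE1_07_48tcv2, which shares at least 20 bases with it, was higher by 5.90 ± 0.43.

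Among the probes well above background on all 12 arrays, FX418534-2-1-1 (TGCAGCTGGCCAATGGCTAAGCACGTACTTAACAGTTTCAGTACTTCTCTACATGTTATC) fell by 2.42 ± 0.29 in the watercored part, and 1 of 36 pairs went the other way. NFR2_21_21mmv2 fell by 2.43 ± 0.47 and lost its call with slide as a block (log2 change -1.42, adjusted p = 0.0806) and in the first year alone (-1.23, adjusted p = 0.158). A set of 30 probes was well above background on all 6 watercored arrays and on none of the 6 normal ones, with a median rise of at least 10.02-fold. The opposite was seen for 12 probes, 11 of them called, with a median fall of at least 3.12-fold.

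In limma, 35363 of 76346 probes differed between the parts, 15930 higher and 19433 lower in watercored flesh (adjusted p = 1.14e-13 for NFW1_05_28tcv2 and 1.64e-08 for FX418534-2-1-1). Of the 4748 probes past 2-fold, 4658 had the same sign in both years. The differences of the 2 years correlated across all probes at r = 0.595, where probes are not independent replicates. With slide as a block, 22877 probes were called, with 3962 at least 2-fold higher and 1025 at least 2-fold lower. With normexp background correction the 2-fold probes were 2254 higher and 237 lower. On the slide that held both parts in the first year, 98.9% of the 2-fold increases and 97.3% of the decreases kept their sign, and in the second year 98.6% and 97.6% did, counted on arrays that also took part in choosing the probes. Each of these slides held 1 watercored and 3 normal arrays.

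The size of the difference between the parts changed with the year for 9895 probes, of which 902 were at least 2-fold more positive and 1535 at least 2-fold more negative in the second year. Opposite signs in the 2 years were seen for 6348 of these probes, but only 719 of them were called in both years. The count depended on the layout, since it was 837 with slide as a block and 5947 when only the groups compared were fitted. Without replicate 2 of the watercored part of the second year it was 5053.

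**Figure D2:**
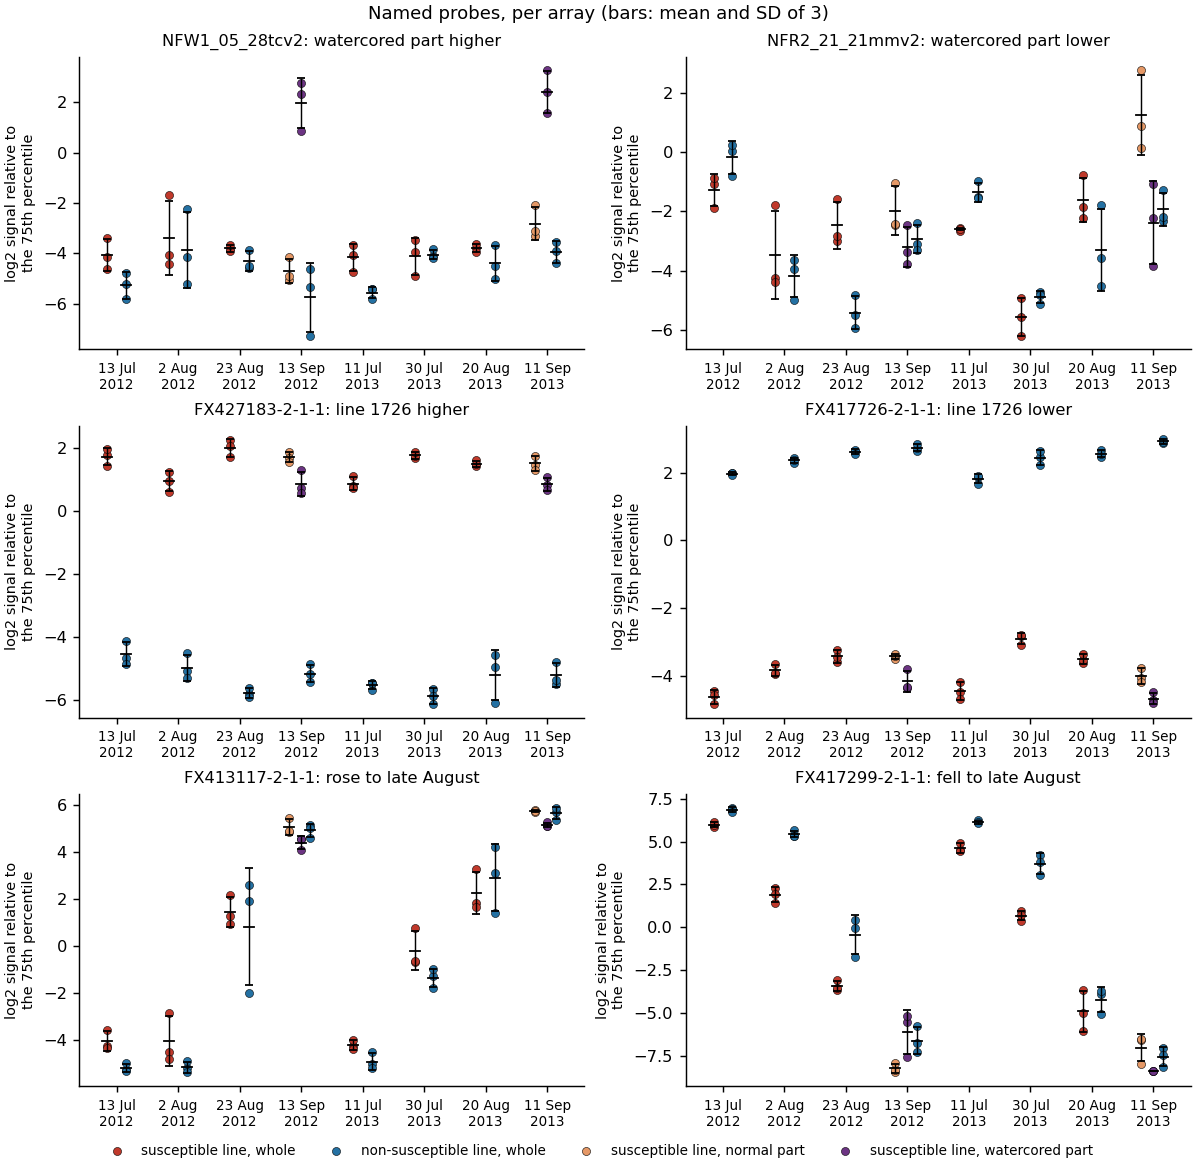
Levels of 6 probes on each array of lines 1726 and 1703 (log2 signal relative to the 75th percentile of the array), with bars for the mean and SD of 3 arrays and the direction of the change in each title. NFW1_05_28tcv2 was above 0 only on the watercored arrays among those drawn, while FX427183-2-1-1 and FX417726-2-1-1 separated the lines at every harvest.

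Probes that differed at least 2-fold between the parts, with 1 sign in both years and measured in both crosses, were followed through the other harvests. The 3042 that were higher in watercored flesh fell from July to late August by a median log2 change of -0.95, and 69.2% were called lower in late August against 12.8% called higher. Random sets of like signal had medians of -0.06 to -0.01, and of all probes measured in both crosses 37.6% were called lower and 39.6% higher. A score per array, the mean of these probes minus the mean of the 673 lower ones, was 2.35 ± 0.43 (SD, n = 3) in the watercored part of the first year and 3.34 ± 0.36 in that of the second. In normal flesh it was -0.85 ± 0.16 and 0.45 ± 0.61, and in line 1703 in September -0.34 ± 0.23 and -0.62 ± 0.21. The arrays of both parts chose the probes, so a gap between watercored and normal flesh was fixed by that choice. Fruit of the first July harvest of each year held 0.91 ± 0.14 and 0.77 ± 0.07 in line 1726, against 1.48 ± 0.09 and 1.23 ± 0.02 in line 1703. Over July and August the score of line 1726 was lower than that of line 1703 by a mean difference of -0.59, with a two-sided permutation p of 1e-05, the smallest the 100000 draws can give (9e-05 adjusted over 9 permutation tests). The mean difference was -0.70 in the first year and -0.49 in the second (exact permutation p = 0.00025 in each, the smallest possible, 0.00075 adjusted). For line 47341 minus line 47377 it was -0.09 (exact permutation p = 0.715, 0.804 adjusted), a mean over opposite signs. On 5 August the score was -0.30 ± 0.25 in line 47341 and 0.17 ± 0.16 in line 47377, and on 20 August 0.46 ± 0.51 and 0.17 ± 0.46. The difference grew by 0.76 between these harvests (exact permutation p = 0.1, 0.15 adjusted).

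**Figure D3:**
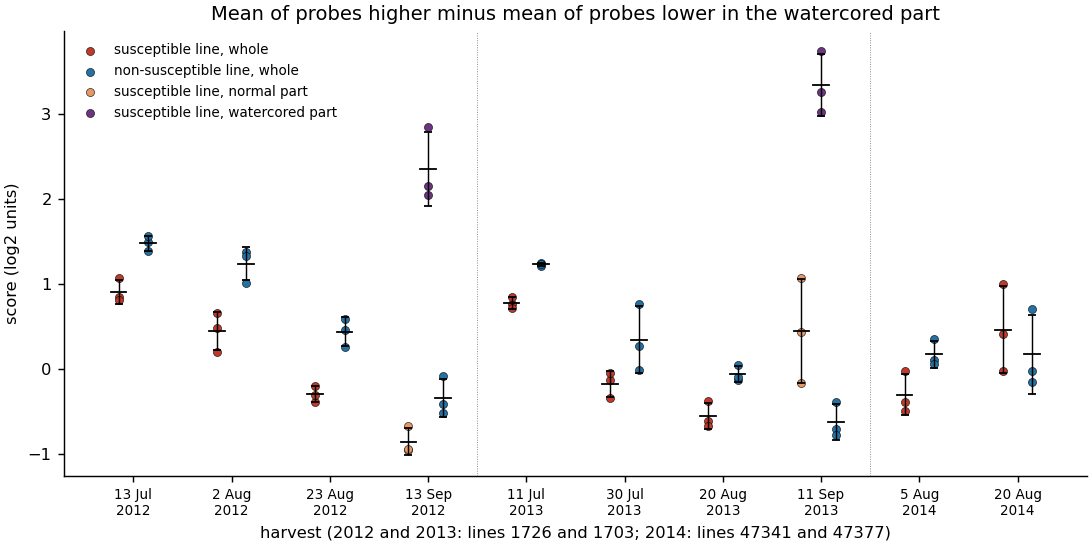
The score of watercored flesh on each array (vertical axis, log2 units) by harvest, for all 66 arrays, with bars for the mean and SD of 3 arrays. Watercored arrays lie highest, at means of 2.35 and 3.34, and their gap to normal flesh was fixed by the choice of probes on these arrays. The score of fruit with no named part, in lines 1726 and 1703, falls from July to late August in both years.

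In September, normal flesh of the susceptible line was compared with fruit of line 1703, for which the labels name no part. This leaves out watercored tissue, but line cannot be told apart from the choice of a part. At least 2-fold higher in normal flesh were 3742 probes, and 3104 were at least 2-fold lower. FX427183-2-1-1 (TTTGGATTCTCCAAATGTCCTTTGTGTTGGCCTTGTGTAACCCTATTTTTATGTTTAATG) was higher by 6.78 ± 0.18 in all 36 pairs of arrays, and FX407900-2-1-1, which shares at least 20 bases with it, by 6.21 ± 0.12. FX395026-2-1-1 (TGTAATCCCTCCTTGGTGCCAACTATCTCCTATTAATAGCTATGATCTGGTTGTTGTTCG) fell by 7.75 ± 0.24, from 6.34 ± 0.26 in line 1703 to -1.41 ± 0.86 in normal flesh (SD, n = 6). FX433831-2-1-1 was lower by a like amount, -7.74 ± 0.23. In this comparison 171 probes were well above background on all normal-flesh arrays and on none of line 1703, with a median rise of at least 12.2-fold, and 169 were the reverse.

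By limma, 36695 probes differed, 15991 higher and 20704 lower in normal flesh (adjusted p = 9.84e-29 for FX427183-2-1-1 and 1.74e-26 for FX395026-2-1-1). Of the 6846 past 2-fold, 6446 had the same sign in both years, although 2-fold increases outnumbered decreases in the first year (4405 and 3668) and not in the second (4580 and 5431). Across all probes, chosen by no threshold, the differences of the 2 years correlated at r = 0.491 and 58.2% had the same sign. With normexp background correction the 2-fold probes were 1866 higher and 1298 lower. Watercored flesh set against line 1703 gave 11562 probes past 2-fold, 6959 higher and 4603 lower. No slide held both groups of this comparison, so slide and group cannot be told apart here.

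The lines were also compared before September, where the labels name fruit without a part. Over the 6 harvests of July and August, 2517 probes were at least 2-fold higher in line 1726 and 2085 at least 2-fold lower. Among the probes well above background on all arrays compared, FX427183-2-1-1 was higher by 6.78 ± 0.10 and FX407900-2-1-1 by 5.87 ± 0.07. FX417726-2-1-1 (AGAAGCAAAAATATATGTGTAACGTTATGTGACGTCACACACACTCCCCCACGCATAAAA) fell by 6.08 ± 0.06, to -3.78 ± 0.63 in line 1726 from 2.29 ± 0.32 in line 1703 (SD, n = 18). Pbr001251.1-3-1 was lower by a log2 change of -4.93 ± 0.24. Each of these 4 probes separated the lines in all 324 pairs of an array of line 1726 and one of line 1703, taken across harvests and years.

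The limma call covered 45112 probes, 24019 higher and 21093 lower in line 1726 (adjusted p = 1.34e-37 for FX427183-2-1-1 and 6.87e-45 for FX417726-2-1-1). Of the 4602 probes past 2-fold, 4118 had the same sign at all 6 harvests. Line differences of the first and second year correlated across probes at r = 0.903, and 2044 probes differed in size between the years. With normexp background correction the 2-fold probes were 971 higher and 1031 lower. With slide as a block 33914 probes were called, and 94.1% to 98.5% of the 2-fold probes kept their sign within the slide that held both lines at each harvest, on arrays that also took part in choosing them.

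**Figure D4:**
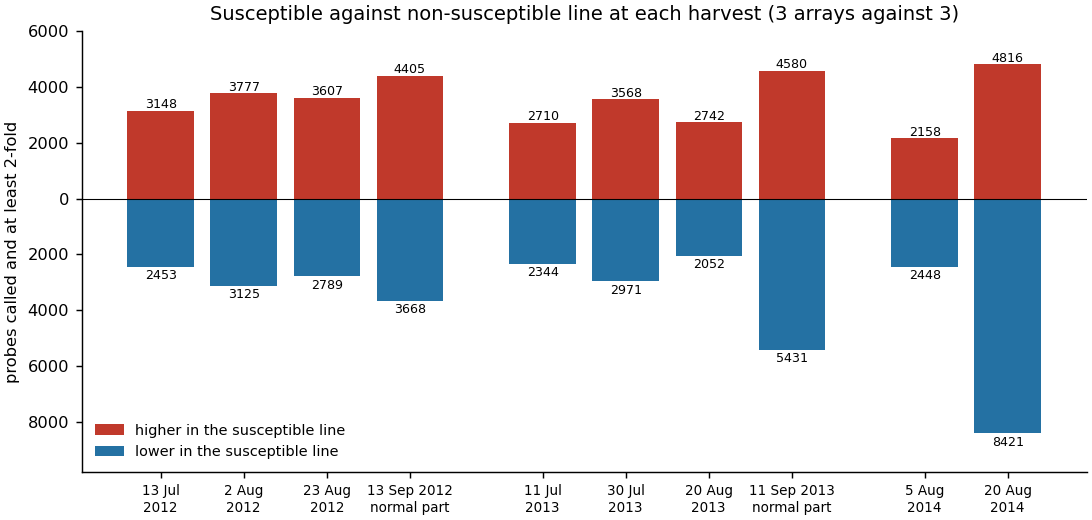
Bars count the probes called and at least 2-fold higher (up) or lower (down) in the susceptible line at each harvest, for 3 arrays against 3, with the normal part standing for line 1726 in September. From July to late August the counts in line 1726 lie between 2052 and 3777, and on 20 August they reach 4816 and 8421 in line 47341.

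Fruit development from July to late August was followed in both lines. Decreases outnumbered increases among large changes, with 9948 probes falling and 4015 rising at least 2-fold, of which 4171 fell and 978 rose at least 4-fold. FX417299-2-1-1 (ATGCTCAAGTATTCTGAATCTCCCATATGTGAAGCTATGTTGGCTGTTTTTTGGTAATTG) fell by 9.16 ± 0.26 and Pbr012748.1-3-1 fell by 9.02 ± 0.27. FX413117-2-1-1 (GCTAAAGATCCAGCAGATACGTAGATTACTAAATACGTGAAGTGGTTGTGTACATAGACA) rose by 6.44 ± 0.33 and FX415080-2-1-1 by 5.92 ± 0.44. Each did so in all 144 pairs of a late August and a July array, taken across lines and years.

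A call was made in limma for 58413 probes, 28896 rising and 29517 falling (adjusted p = 1.93e-28 for FX417299-2-1-1 and 2.40e-20 for FX413117-2-1-1). Of the 13963 past 2-fold, 13480 had the same sign in both lines and both years. After quantile normalization the 2-fold probes were 6253 rising and 8361 falling, or 42.8% rising in place of 28.8%, and the median change of all probes moved from -0.01 to 0.14. The balance of all calls depended on the processing, with 36593 rising and 23627 falling after quantile normalization and 24407 rising and 35218 falling with normexp. No slide held July and late August fruit of one line, so slide and harvest cannot be told apart.

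The course from July to late August differed between the lines for 11834 probes, 2887 of them by at least 2-fold. The fall or rise was larger in line 1703 for 5612 of these, larger in line 1726 for 2941, and of opposite sign for 3281, of which 720 were called in both lines. Across all probes the changes of the lines correlated at r = 0.904. With slide as a block, 3265 probes differed, 1626 of them by at least 2-fold.

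In the Taihaku by Akiakari cross, line 47341 was compared with line 47377. Decreases were in excess, with 5325 probes at least 2-fold lower and 3209 at least 2-fold higher in the susceptible line. NLE2_18_51tcv2 (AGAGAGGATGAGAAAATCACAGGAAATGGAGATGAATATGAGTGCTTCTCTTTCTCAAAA) was higher by 8.05 ± 0.13, at 3.22 ± 0.29 in line 47341 against -4.84 ± 0.25 in line 47377 (SD, n = 6), and FX419924-2-1-1 was higher by 6.46 ± 0.15. FX414231-2-1-1 (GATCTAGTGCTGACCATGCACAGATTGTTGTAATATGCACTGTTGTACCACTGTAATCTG) fell by 5.90 ± 0.14 and FX414118-2-1-1 fell by 5.64 ± 0.17. Late in August the difference was wider, with 13237 probes past 2-fold on 20 August and 4606 on 5 August, and 3049 probes differed between these dates by a test of the difference. The arrays of line 47341 on 20 August also had the widest spread of any group, with r down to 0.957 and a median SD of 0.30, where that of the other groups was at most 0.17.

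The limma call held 31898 of 72375 probes, 12978 higher and 18920 lower in line 47341 (adjusted p = 2.88e-11 for NLE2_18_51tcv2 and 3.90e-10 for FX414231-2-1-1). With slide as a block 17419 probes were called, 2603 of them at least 2-fold higher and 3479 at least 2-fold lower. Within slides, 97.4% of the 2-fold increases and 96.9% of the decreases kept their sign on 5 August, and 99.7% and 99.51% did on 20 August, again on arrays that took part in choosing the probes, so a high share was expected. With normexp background correction the 2-fold probes were 2303 higher and 2501 lower. After quantile normalization 45.8% of the 2-fold probes were higher, in place of 37.6%, so the size of the excess depended on the processing.

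Whether the line differences recurred in both crosses was examined over the 71030 probes measured in each. The same direction was seen for 9325 probes, 4285 higher and 5040 lower in both susceptible lines, where independence of the crosses would give 9281. Opposite directions were seen for 10257, where independence would give 9476. Across probes the line differences of the 2 crosses correlated at r = -0.0443. Past 2-fold in both crosses, 223 probes were higher and 372 lower in both susceptible lines, where independence would give 90.01 and 127. Opposite past 2-fold were 485 probes higher in line 1726 and lower in line 47341, and 286 the reverse, where independence would give 150 and 76.6.

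Pbr005319.1-3-1 (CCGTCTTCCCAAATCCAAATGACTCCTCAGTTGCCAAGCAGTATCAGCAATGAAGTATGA) was higher by 4.26 ± 0.06 in line 1726 and by 4.82 ± 0.08 in line 47341. Pbr041346.1-3-1 was higher by 2.98 ± 0.09 and by 2.76 ± 0.24. Of the shared decreases, Pbr042849.1-3-1 (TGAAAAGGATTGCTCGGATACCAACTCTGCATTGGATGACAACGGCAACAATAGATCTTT) fell by 2.88 ± 0.06 and by 3.41 ± 0.17, and FX394636-2-1-1 fell by 2.78 ± 0.07 and by 3.32 ± 0.18. With slide as a block in both fits, 4247 probes shared a direction and 4159 were opposite, so the order of these counts turned.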

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

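The test of the normal part, the splits with mean effects taken out and the test of constant line differences were chosen after their results had been seen. A condition added to the last of these, that the late-August lead be at least that of July, also came after its result, and moved the reading from support to undecided. The bootstrap bound on the second-probe test was likewise added afterwards and left its reading as it was.

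The excess of increases over decreases among differences of at least 2-fold in watercored flesh was set against 3 technical explanations. Quantile normalization in place of scaling on the 75th percentile left 75.3% of the 2-fold probes as increases, against 83.0%. In each year 1 slide held both parts, with 1 watercored and 3 normal arrays. Between these, probes chosen in the other year kept at least 95.3% of their median difference, which rests on a single watercored array per year. Decreases lost near the background would restore the balance among bright probes, yet 84.7% of the 2-fold probes brighter than the median were increases. All 3 tests argue against these explanations as the whole cause. A real excess of increases among differences of at least 2-fold in watercored flesh remains a hypothesis, with a change in the mix of cells in that tissue untested. Over all calls, of any size, decreases were more frequent, with 19433 probes lower and 15930 higher.

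Line differences seen at all 6 harvests of July and August could arise from sequence differences between the lines under single probes. A non-overlapping probe of the same sequence ID followed a 2-fold line difference in 70.1% of 364 cases and a 2-fold difference between the parts in 82.6% of 426, a ratio of 0.848 (95% bootstrap interval 0.778 to 0.918). That is above 0.5, the bound set beforehand for such differences as the whole cause, although the interval includes the bound of 0.8 set against any part of it. Changes of the paired probes correlated at r = 0.558 for the lines, against 0.769 for the parts and 0.778 for July to late August. Within slides that held both lines, probes chosen in the other year kept at least 98.0% of their fold, which argues against a slide difference. Differences in transcript level between these genotypes stay open as the biological explanation, and a smaller part due to sequence was not excluded.

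On a July to late August axis taken from the other year, line 1726 was ahead of line 1703 in July by 0.23 and 0.50 in the first and second year, at the second harvest by 0.55 and 0.61, and in late August by 0.14 and -0.01. Within slides that held both lines at the first 2 harvests, the mean lead was 93.6% of that between all arrays, which argues against a slide difference. Constant line differences at the axis probes could give a lead at each harvest. The lead in July minus that in late August had exact permutation p of 0.825 and 0.05 in the 2 years. Labels exchanged within harvests carry the line difference itself into that spread, and a p that misses the threshold shows no absence. The test thus cannot tell constant line differences from an earlier start. Faster early development of line 1726 remains a hypothesis.

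The July to late August change differed between lines 1726 and 1703 for 11834 probes by a test of the difference. The watercored difference changed with the year for 9895 probes. The line difference of July and August changed with the year for 2044 probes, 581 of them with opposite signs, of which 93 were called in both years. In the Taihaku by Akiakari cross, the later one, the line difference changed between the harvests for 3049 probes. Of these, 1577 had the larger difference on 20 August and 145 on 5 August. Opposite signs at the harvests were seen for 1327, of which 130 were called at both. FX418534-2-1-1 fell by 1.57 in watercored flesh of the first year and by 3.27 in that of the second, a difference between years of -1.70 (adjusted p = 0.0499). That p lies just under 0.05, in a comparison whose number of calls depended on the layout. Alternatives were not run for the year difference of this probe. Pbr041346.1-3-1 was higher in line 47341 by 3.80 on 20 August and 1.71 on 5 August, a difference of 2.09 (adjusted p = 0.0429). Pbr042849.1-3-1 was lower in line 1726 by a log2 change of -3.17 in the first year and -2.60 in the second, a difference of 0.57 (adjusted p = 0.00435). The score of the 2170 higher and 269 lower probes that passed 2-fold between the parts in each year, normal flesh minus line 1703, was 1.94 higher in the second year than in the first (exact permutation p = 0.015, 0.0338 adjusted).

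Chance was examined by exchanging labels, with 100 splits per comparison including the real one, on probes with a value on every array. Chance was excluded for watercored against normal flesh, where 1 split reached the real count of 35290 and the highest other gave 21870. For normal flesh against line 1703, 1 split reached 36589 and the highest other gave 24970. Between the lines in July and August, 1 split reached 44982 and the highest other gave 13760. For July to late August, 1 split reached 58253 and the highest other gave 46852. In the later cross, 1 split reached 31895 and the highest other gave 14459. For the difference between lines in the July to August change, 3 splits reached 11819, the real one included, and the highest other gave 19259. The share was under 0.05, the bound written beforehand, but labels exchanged within harvests carry the line difference itself into these splits. They were not rerun with that difference taken out, so chance was left undecided there, a reading set after the result had been seen. For the difference between years in the watercored comparison, 16 splits reached 9884, so chance was not excluded there. The highest of these gave 36538, several times the real count, and points to a structure of the samples, since such splits carry the mean effects of year and part. Once these mean effects were taken out, 1 split reached 9884 and the highest other gave 3510. For differences shared by the crosses, 1 split reached 9323 and the highest other gave 3788, but this count says nothing about sharing. Exchanging labels in the later cross lowers its calls and with them any overlap, so the bound written beforehand was wrong. The reading was changed to undecided after the result had been seen, and independence of the crosses would give 9281 where 9325 were reported.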

How the results depend on the processing

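All alternatives were chosen beforehand. Outside the runs that left out an array, 86 counts stayed within 1.5 times the reported count and 34 did not, 204 values of named probes kept direction and call, and 2 values of NFR2_21_21mmv2 lost the call as given in the report. No named probe reversed under any alternative. With each array left out in turn, 358 counts stayed within 1.5 times and all 576 values of named probes kept direction and call. The 2 exceptions concern the difference between years in the watercored comparison without replicate 2 of the watercored part of the second year, where 5053 probes were called (range over the 12 arrays 5053 to 11383), 1622 of them at least 2-fold (range 1622 to 3073), and the cause was not tested.

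With normexp the probes past 2-fold were 2491 for watercored against normal flesh, 3164 for normal flesh against line 1703, 2002 for the lines in July and August, 9070 for July to late August, 1584 for the difference between lines in that change, 1280 for the difference between years and 4804 for the later cross. The cause was not tested. It kept the direction of the excess except for the lines, where increases became fewer than decreases. The authors' table holds fewer probes, 28101, so by construction fewer were called. In the same order it gave 12120, 12374, 15201, 19308, 4228, 3596 and 10322 calls, of which 1460, 2099, 1425, 4402, 824, 773 and 2624 were at least 2-fold. Of line differences in both crosses, 3172 shared a direction and 3450 were opposite there.

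Slide as a fixed block spends degrees of freedom on 17 slides. Calls were then 22877 for watercored against normal flesh, 3265 for the difference between lines in the July to August change (1626 past 2-fold), 837 for the difference between years (642 past 2-fold), 17419 for the later cross, 4247 shared by the crosses and 4159 opposite. As a random block, slide gave 40564 calls for normal flesh against line 1703 and 60422 for July to late August. The slide correlation used was negative (-0.0784), and no slide held both sides of these comparisons. These counts therefore do not show that the calls are free of slide. With only the groups compared, the difference between years gave 5947 calls, 1536 past 2-fold, from fewer arrays. Watercored in place of normal flesh gave 11562 probes past 2-fold against line 1703, which is another comparison by construction.

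A replicate block gave 34665 calls for watercored against normal flesh, 44517 for the lines and 26857 for the later cross, each within 1.5 times. The labels do not say that a number marks shared fruit, and among 42 pairs of arrays of like number and harvest 16 had an r across probes over 0.1 (range -0.433 to 0.320), so numbers were not taken to pair samples. The like number correlated best in 19 of the 42, against 14 by chance, and in 5 of the 6 pairs of watercored and normal flesh, against 2 by chance (r from -0.00592 to 0.320), a hint that parts of like number may share fruit. The gene list tests and their alternatives were not run, because the files give no gene name or description beyond the probe ID. Signal over background limits what was seen to 67.3% to 76.5% of spots per array, and only the folds given for probes seen on 1 side of a comparison are bounds.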

Other observations

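The tests of the normal part and of growth between harvests in the later cross were chosen after their results had been seen. Readings and 1 displayed value of other tests were changed afterwards, as stated with them.

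Large and steady line differences of July and August were mostly carried into September. Of the 1928 probes at least 2-fold higher in line 1726 on average, with the same sign at all 6 harvests and measured in both crosses, 79.0% were called higher in its normal flesh against line 1703, with a median log2 difference of 1.18. Of the 1666 lower ones, 72.8% were called lower, with a median of -1.18. Of all probes measured in both crosses, 21.2% were called higher and 28.1% lower in that comparison. Without any choice of probes, the line differences of July and August and those of September correlated at r = 0.642, and 65.3% had the same sign. In line 47341 against line 47377, the 1928 higher probes had a median of -0.30 (random sets of like signal -0.14 to -0.09) and the 1666 lower ones a median of -0.02 (random sets -0.12 to -0.07). Among the 3377 probes that fell at least 2-fold from late August to September in line 1703, the median difference of line 47341 from line 47377 was -0.27 on 5 August (random sets -0.06 to -0.03) and -1.41 on 20 August (random sets -0.17 to -0.12), and the median change from 5 to 20 August over these 2 lines was -1.29. The 1930 probes that rose in line 1703 had medians of 0.09, 0.54 and 0.62 in the same comparisons.

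That watercored flesh is further along ripening than normal flesh was tested with probes that changed at least 2-fold from late August to September in line 1703. Those that fell should then be lower in watercored flesh and those that rose higher. Instead the fallers had a median log2 difference of 0.28 and the risers one of -0.18, each on the other side of the interval from 10000 random sets of like signal. The test argues against advanced ripening of watercored flesh, as far as change in line 1703 stands for ripening. The 7865 probes that fell from July to late August in the lines 1726 and 1703 likewise had a median of 0.27 in watercored flesh, and the 3774 that rose one of -0.18. A candidate explanation is that watercored flesh regained part of the expression of younger fruit, which was not tested on other samples.

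A presence of the watercored change in susceptible fruit before September was tested with the score of watercored flesh. It would make the score higher in line 1726 than in line 1703 in July and August and higher in line 47341 than in line 47377. The difference in the first cross was -0.59, of the opposite sign, so the predicted higher score was not seen in line 1726. A constant difference between the genotypes at these probes, or a lead of line 1726 in development, could mask an early presence. The test therefore cannot decide on it in line 1726, a reading set after the result had been seen. In the later cross the mean difference was -0.09 (exact permutation p = 0.715), from scores of -0.30 in line 47341 and 0.17 in line 47377 on 5 August and of 0.46 and 0.17 on 20 August. The difference thus turned to the side of the hypothesis at the late harvest, with a growth of 0.76 (exact permutation p = 0.1), which leaves the later cross undecided. The first display of this test carried the value of the later cross, and that of the first cross replaced it, a step that left the reading unchanged.

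Normal flesh of the second year may have carried more of the watercored change than that of the first. The score of probes past 2-fold in each year, normal flesh minus line 1703, was 1.94 higher in the second year, and it was 1.61, 1.95 and 2.26 higher without replicates 1, 2 and 3 of the normal flesh of the second year. On this score watercored flesh of line 1726 also rose between the years, from 1.71 ± 0.57 to 2.94 ± 0.36 (SD, n = 3). Normal flesh rose from -2.13 ± 0.16 to -0.49 ± 0.65, and line 1703 went from -1.67 ± 0.28 to -1.96 ± 0.26. Both parts thus rose, and a shift of line 1726 with the year was not told apart from a change of normal flesh alone. With probes chosen in the other year, normal flesh lay at 42.0% of the distance from line 1703 to watercored flesh in the second year and at -9.12% in the first. Each year's normal flesh lay on 1 slide, so that slide and year cannot be told apart, and neither can traces of watercored tissue and an early stage of the disorder.

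Whether line 47341 moved ahead of line 47377 on the July to late August axis between 5 and 20 August stays open. The lead grew by 0.75 (exact permutation p = 0.28, smallest possible 0.005). A bound written beforehand would have read a p of 0.05 or more as evidence against the hypothesis. That bound was wrong, because labels exchanged within harvests carry the line difference itself into the spread, and because a p that misses the threshold shows no absence. The reading was therefore changed to undecided after the result had been seen.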
